A study of Mus musculus with 12 samples.

How the data were processed

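RNA was measured by sequencing in 12 libraries from 6 mice at postnatal day 5, with 3 animals per genotype and a rostral and a caudal library from each animal. Per the labels' protocols, cortex with hippocampal formation was separated from the ventral forebrain and divided into a rostral and a caudal piece, RNA was extracted with RNeasy kits, mRNA was captured from total RNA, and KAPA mRNA HyperPrep libraries were read as paired ends of 50 bases on a NovaSeq instrument. Per the submitters' processing notes, reads were handled with STAR 2.7.8a and featureCounts 2.0.3 on genome build GRCm39. The annotation release, the strand setting and the handling of reads with several alignments are not given in the sources used here.

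The deposited table holds expected counts for 55357 genes, of which 42419 had a count in at least 1 library. Between 9.69% and 14.3% of the values of a library were fractional, so the deposited values are not plain read counts. Shared reads may have been divided between genes, but how is not given. The values were rounded to whole numbers before the tests. Whole counts had been planned for, and the planned tests were kept. Total counts ran from 43810241 to 87170063 per library. Gene symbols, identifiers and coordinates were taken as the table gives them. Because reads may have been divided between genes, values of near-identical copies (7SL and 7SK RNA genes, mitochondrial genes with nuclear copies) are uncertain. Overlapping or antisense genes may not be told apart since the strand setting is not known.

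Groups were taken from the labels: control (T4, T8 and T70) and cKO (T3, T6 and T80), rostral and caudal. Rostral and caudal libraries with the same T number were taken to come from the same animal. The deviations of the 2 libraries of an animal from their group means, correlated across genes, gave r = 0.27 for T4, 0.247 for T8, 0.333 for T70, 0.0306 for T3, -0.00254 for T6 and 0.461 for T80. The sex of each animal was read from Xist and Y-linked transcripts.

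Each comparison was fitted with edgeR 4.0.16 in R 4.3.3 on the libraries of its own groups only: genes were kept with filterByExpr, libraries were scaled by TMM, and the robust quasi-likelihood F test was used with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. The comparisons were genotype in rostral cortex, genotype in caudal cortex, genotype on the sum of each animal's rostral and caudal counts, region in control, region in cKO, and the interaction of genotype and region on all 12 libraries. The region comparisons and the interaction were fitted without the animal in the model, so their p-values leave out the pairing of libraries. Counts scaled to library size (CPM) beside a comparison were scaled within it, and those of Egfr per library were scaled over all 12 libraries. The correlation of the rostral and caudal log2 fold changes was taken across genes, which are not independent replicates.

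A set of 37 gene lists for cell types, brain regions, signalling and metabolism, with 567 genes, was fixed before the data were examined, as were the tests, the samples in each fit, the rule for named genes and the first set of alternatives. Of the list genes, 4 had no match in the table. Lists with 5 or more tested genes were tested with camera of limma 3.58.1 on log2 CPM values with a prior count of 3 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera was repeated with a correlation estimated for each list, and fry was run beside it. For each list the number of members past 0.05 was counted after adjustment over all genes and adjusted over the list alone. List levels per library are mean log2 differences from the control mean of the same region.

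The genes named in the text are Egfr, and per main comparison up to 10 higher and 10 lower genes by the size of the log2 fold change among genes with an adjusted p under 0.05, a mean CPM of 1 or more, groups that did not overlap, and a symbol that is not a model name. For the summed counts, region in cKO and the interaction the limit was 5 each way. Where fewer than 5 passed in a direction, the genes with the smallest unadjusted p filled the list to 5 and are named as not passing. Up to 4 members with the smallest p were taken from each list described. Sex-linked genes were kept out.

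The first set of alternatives was DESeq2 1.42.0, RLE and upper-quartile scaling, no filter on low counts, a filter of 1 CPM in 3 libraries, each animal left out in turn, sex or the range of the T number as a covariate, 1 fit over all 12 libraries, limma voom with duplicateCorrelation for the average of both regions, and the animal as a block for the region comparisons and the interaction. Library quality weights, the removal of single cKO libraries, the removal of mitochondrial genes and an exchange of the region labels of T3 were added after the data were seen.

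The tests were tested on simulated counts with the means, spreads and library sizes of these libraries and 200 changed genes. Each gene was drawn independently, with the same spread in every library. No simulated library could therefore depart over many genes at once, as cKO rostral T6 did. The recovered shares and false calls need not hold for the real data. For genotype in caudal cortex (20624 genes) edgeR recovered 38.8% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 97.0% of those changed 4-fold, with 12 false calls, where DESeq2 made 50. For genotype in rostral cortex (20518 genes) the shares were 4.48%, 49.3% and 84.9%, with 9 false calls. For the region difference in control (20373 genes) they were 68.7%, 92.5% and 97.0%, with 20 false calls. For the region difference in cKO (20806 genes) they were 1.49%, 34.3% and 95.5%, and for the interaction (21293 genes) 2.99%, 26.9% and 89.4%. The spread between animals exceeded counting error: for genes with 100 or more counts, the squared difference between replicate libraries per gene was 11.5 to 39.3 times that of counting error in the 8 pairs without a library of T6, 88.8 and 104 times in the caudal and 336 and 365 times in the rostral pairs that hold a library of T6. These are means over genes, scaled by total counts and not by TMM. Those with cKO rostral T6 (TMM factor 0.835) therefore also hold its shift in scale and its mitochondrial counts. Genome coordinates of another build were not used here. Some genes that the rule for named genes takes are not reported here.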

Results

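Messenger RNA was sequenced from mouse cortex and hippocampal formation at postnatal day 5, in control animals and in animals with a brain-specific deletion of Egfr, the epidermal growth factor receptor, made with a Nestin-driven recombinase (cKO). The tissue of each animal was divided into a rostral and a caudal piece. There were 12 libraries in 4 groups, with 3 animals in each: control T4, T8 and T70, and cKO T3, T6 and T80. Total counts per library ran from 43810241 (cKO caudal T3) to 87170063 (cKO rostral T6). Sex was unequal, with 2 females and 1 male among the controls and 1 female and 2 males among the cKO animals. The labels name the controls both as heterozygous for the floxed allele and as wild type, and do not say whether they carry the recombinase. If they do not, the comparisons of genotype cannot tell the loss of Egfr apart from the presence of the recombinase.

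The cKO rostral library of T6 stood apart from its group over many genes, and that of T3 in choroid plexus and hippocampal transcripts. The median absolute log2 deviation of a gene from the mean of the other libraries of the group was 0.403 in T6, 0.236 in T3 and 0.247 in T80. In the cKO rostral library of T6, mitochondrially encoded genes took 8.18% of all counts, against 1.85% to 3.98% in the other 11 libraries. Nuclear copies of these genes, to which part of the mitochondrial reads may have been assigned, took a further 4.49% there and 1.38% to 2.64% elsewhere. The cKO rostral library of T3 held 26689 counts of Ttr, the thyroxine carrier made by the choroid plexus, where the control rostral libraries held 3 to 22 and the other cKO rostral libraries 6 and 26. On a score over the genes that differed between control regions, with 0 at the control rostral mean and 1 at the control caudal mean, the cKO rostral libraries lay at 0.855 (T3), -0.0783 (T6) and 0.638 (T80), and the cKO caudal libraries at 0.557 (T3), 1.15 (T6) and 0.811 (T80).

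**Figure D1:**
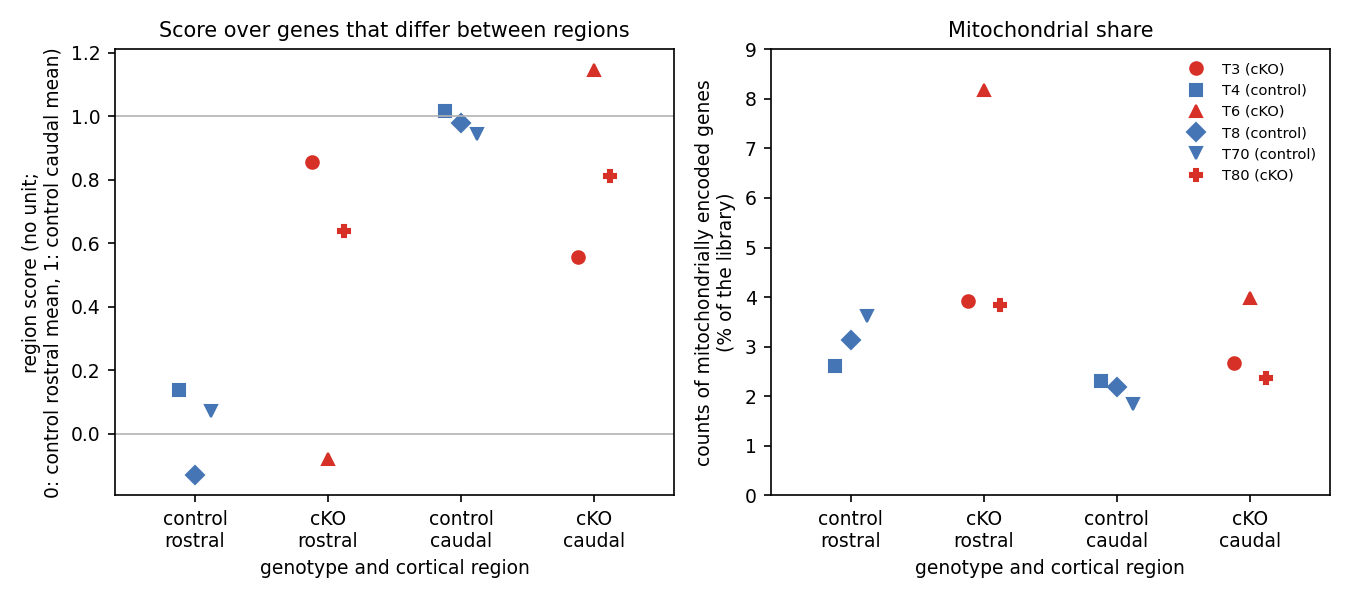
On the left, region score of each library (no unit), over the genes that differed between control rostral and caudal cortex, where 0 is the control rostral mean and 1 the control caudal mean, and right, counts of mitochondrially encoded genes as a percent of each library. Each point is 1 library with the animal given by its symbol, and cKO rostral T6 lies at 8.18%.

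The level of Egfr itself, the gene targeted by the deletion, checks the genotype of each library. Egfr (ENSMUSG00000020122.17, chromosome 11, 16702203 to 16868158, GRCm39) was at 43.4 ± 4.91 CPM (read counts scaled to library size, SD, n = 3) in control rostral and 41.7 ± 3.26 CPM in control caudal cortex. In cKO it was at 9.77 ± 3.14 CPM in rostral cortex, 22.5% of control, and at 9.98 ± 4.49 CPM in caudal cortex, 24.0% of control. Every cKO library (5.73 to 14.7 CPM) lay below every control library (39.3 to 49.0 CPM). On the summed counts of each animal Egfr fell by 2.10 on the log2 scale (SE 0.11, adjusted p = 0.0019, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 per genotype). In the separate regions the log2 fold change was -2.14 (SE 0.25, adjusted p = 0.186) in rostral and -2.05 (SE 0.31, adjusted p = 0.102) in caudal cortex by the same edgeR test, so Egfr did not pass there. This depended on the fit: DESeq2 called it in rostral (adjusted p = 6.34e-13) and caudal cortex (2.51e-12). With single animals left out, edgeR called it in rostral cortex only without T6 (adjusted p = 0.0027). In caudal cortex it passed only without T3 (edgeR adjusted p = 0.0192) or T6 (0.0306). The counts cover all exons of the gene, and which exons were deleted is not given in the sources used here.

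**Figure D2:**
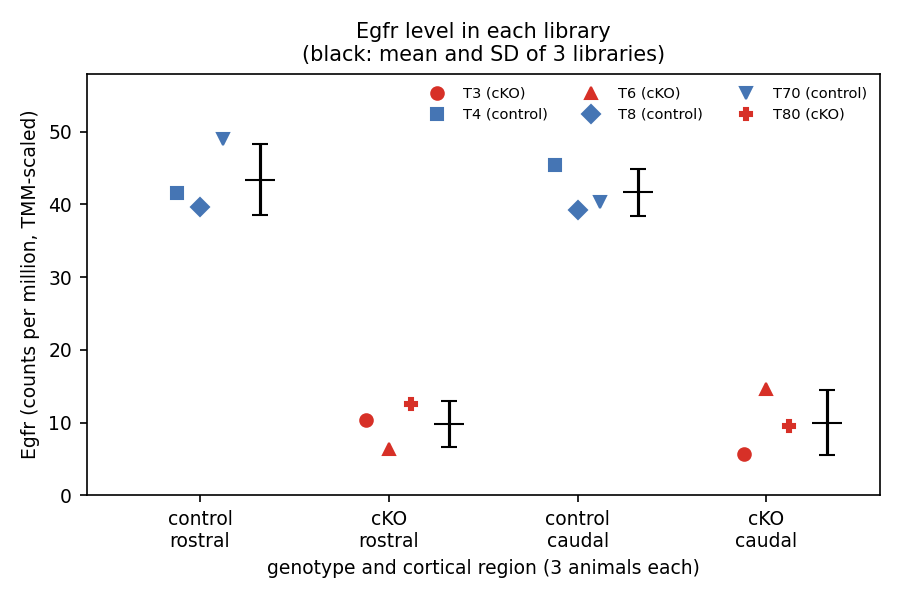
Egfr in each of the 12 libraries, in TMM-scaled CPM, by genotype and region, with the animal given by the symbol. Black bars are the mean and SD of 3 libraries, and all cKO libraries lie between 5.73 and 14.7.

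The comparison of cKO with control rostral cortex asks which transcripts differ between the genotypes in the rostral part of the forebrain. Kcnj10, the potassium channel of astrocyte membranes, was at 47.1 ± 7.38 CPM (SD, n = 3) in cKO and 107 ± 1.63 CPM in control, a log2 fold change of -1.18 (SE 0.12). Olig1, a transcription factor of the oligodendrocyte lineage, was at 52.3 ± 8.64 against 113 ± 2.54 CPM (log2 fold change -1.12, SE 0.13). Serpina3n, a protease inhibitor induced in reactive astrocytes, was at 5.61 ± 0.51 against 1.59 ± 0.37 CPM (1.82, SE 0.21), and Neurod1, a transcription factor of young neurons, at 31.1 ± 4.72 against 13.7 ± 1.56 CPM (1.18, SE 0.15). Other genes with the smallest p were Galnt6 (2.72), Cr2 (2.55) and Dgkg (1.33) on the higher side and Wdfy1 (-0.74) and Fgfbp3 (-1.38) on the lower side. None of these genes passed, each with an adjusted p of 0.186 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 per genotype), which was the lowest of the comparison. All of them but Wdfy1 also differed between the control regions, in the direction of caudal cortex: Neurod1 was at 40.6 CPM in control caudal and 14.3 CPM in control rostral cortex and Cr2 at 5.01 and 0.775 CPM, and the log2 difference was 1.39 for Serpina3n, 1.28 for Galnt6, 1.54 for Dgkg, -0.52 for Kcnj10, -0.50 for Fgfbp3 and -0.36 for Olig1. The cKO rostral libraries of T3 and T80 also scored towards caudal cortex over all region genes (0.855 and 0.638), while that of T6 (-0.0783) did not, with Neurod1 at 27.4 CPM and Cr2 at 2.86 CPM.

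The edgeR test called 0 of 20599 genes in rostral cortex, with 1955 at an unadjusted p under 0.05, of which 1135 were higher and 820 lower. DESeq2 called 394 genes and limma voom with library quality weights 974. The groups did not overlap for 19.7% of the genes, where chance gives 10%. The cKO rostral library of T6 decided this count: without animal T6, 1058 genes passed in edgeR, 693 higher and 365 lower, and without animal T3, 7 passed. Without T6 the cKO group is T3 and T80, whose rostral libraries scored 0.855 and 0.638 towards caudal cortex. Genes that differ between the regions may thus be among the 1058, which was not tested.

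Of the 37 gene lists, 12 passed camera in rostral cortex, 5 higher and 7 lower in cKO, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.346. No member of any list passed over all genes. The astrocyte list had a median log2 fold change of -0.39, with 23 of 25 members lower (adjusted p = 7.47e-07, camera, and adjusted p = 0.745 with an estimated correlation) and 0 members past the test adjusted over the list alone. Among its members Slc7a10, a neutral amino acid transporter, was at -1.74 (SE 0.42) and Aldh1l1, a folate enzyme of astrocytes, at -1.14 (SE 0.31). Its level in the separate cKO rostral libraries was -0.0330 in T3, -1.82 in T6 and -0.386 in T80.

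The 3 lists of the oligodendrocyte lineage lay lower in cKO rostral cortex in each animal. The precursor list had a median of -0.48, with 12 of 14 members lower (adjusted p = 5.41e-06, camera, and adjusted p = 0.398 with an estimated correlation). Adjusted over the list alone 4 lower members passed, and Olig2 was at -0.70 (SE 0.09). The list of newly formed oligodendrocytes had a median of -0.48, with 11 of 12 members lower (adjusted p = 9.05e-06, camera, and adjusted p = 0.408 with an estimated correlation) and 6 past the test adjusted over the list alone. In it Enpp6 was at -1.79 (SE 0.43) and Bcas1 at -1.10 (SE 0.28). The myelinating list had a median of -0.55, with 10 of 14 members lower (adjusted p = 1.32e-06, camera, and adjusted p = 0.489 with an estimated correlation) and 7 past the test adjusted over the list alone. Its members include the myelin gene Mbp (-0.54, SE 0.13) and the galactolipid enzyme Ugt8a (-0.85, SE 0.19). The level of the precursor list was -0.328 in T3, -0.706 in T6 and -0.482 in T80, and that of the myelinating list -0.239, -1.33 and -0.840. All 3 lists also had a median below 0 in control caudal against control rostral cortex (-0.23, -0.26 and -0.34). The cholesterol synthesis list lay at a median of -0.44 with 18 of 18 members lower (adjusted p = 1.89e-07, camera, and adjusted p = 0.661 with an estimated correlation). Adjusted over the list alone 0 of them passed. The level of the list was -1.10 in T6 against -0.259 in T3 and -0.224 in T80.

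Lists of activated microglia and reactive astrocytes lay higher in cKO rostral cortex. The reactive astrocyte list had a median of 1.49, with 15 of 15 members higher (adjusted p = 5.5e-07, camera, and adjusted p = 0.398 with an estimated correlation) and 9 past the test adjusted over the list alone. Osmr, the oncostatin M receptor, was at 0.65 (SE 0.15) and Steap4 at 2.49 (SE 0.57). The activated microglia list had a median of 1.05, with 13 of 14 members higher (adjusted p = 1.32e-06, camera, and adjusted p = 0.346 with an estimated correlation) and 9 past the test adjusted over the list alone. Spp1, the secreted phosphoprotein osteopontin, was at 2.72 (SE 0.63), Clec7a at 2.35 (SE 0.49) and the lysosomal glycoprotein Cd68 at 1.19 (SE 0.25). The level of the activated microglia list was 1.29 in T3, 1.01 in T6 and 1.54 in T80, where the control rostral libraries lay between -0.317 and 0.338. In the cKO rostral libraries the microglia list was at 1.01 in T3, -0.682 in T6 and 0.759 in T80, and it did not pass camera (adjusted p = 0.0791). The meningeal fibroblast list spread more between these libraries, at 1.18 in T3, -3.56 in T6 and 1.52 in T80, and the choroid plexus list at 3.21, -0.697 and 0.860.

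The other lists called in rostral cortex hold genes of neurons, blood and mitochondria. The cortical interneuron list had a median of 0.35, with 13 of 17 members higher (adjusted p = 0.00143, camera, and adjusted p = 0.346 with an estimated correlation) and 2 past the test adjusted over the list alone. Erbb4, a receptor for neuregulins, was at 0.49 (SE 0.09). The immediate early list had a median of 0.29, with 14 of 15 higher (adjusted p = 0.00163, camera, and adjusted p = 0.661 with an estimated correlation), and Bdnf was at 0.96 (SE 0.23). Both lists also lay higher in control caudal than in control rostral cortex. Relative to the control rostral mean, the interneuron list was at 0.328 to 0.483 in control caudal and 0.226 to 0.433 in cKO rostral libraries. The immediate early list was at 0.233 to 0.332 and 0.0997 to 0.603. The striatum list had a median of -0.95, with 14 of 16 lower (adjusted p = 3.16e-05, camera, and adjusted p = 0.661 with an estimated correlation). Adjusted over the list alone 2 of them passed. Its level already differed between control rostral libraries, at 0.794 in T4, -1.02 in T8 and 0.223 in T70. The mitochondrially encoded list had a median of 0.86, with 13 of 13 higher (adjusted p = 0.000133, camera, and adjusted p = 0.745 with an estimated correlation) and a level of 1.53 in T6 against 0.232 in T3 and 0.293 in T80. The erythroid list, at a median of -0.38 with 9 of 10 lower, passed camera with all animals (adjusted p = 0.0106, and adjusted p = 0.661 with an estimated correlation) but not without T8 (adjusted p = 0.0696) or T3 (adjusted p = 0.159). Without T6, 20 lists passed. The test direction was down while median and mean lay above 0 for the pan-neuronal (median 0.06), olfactory bulb (0.03), endothelial (0.01) and meningeal fibroblast (0.79) lists, none of which passed.

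**Figure D3:**
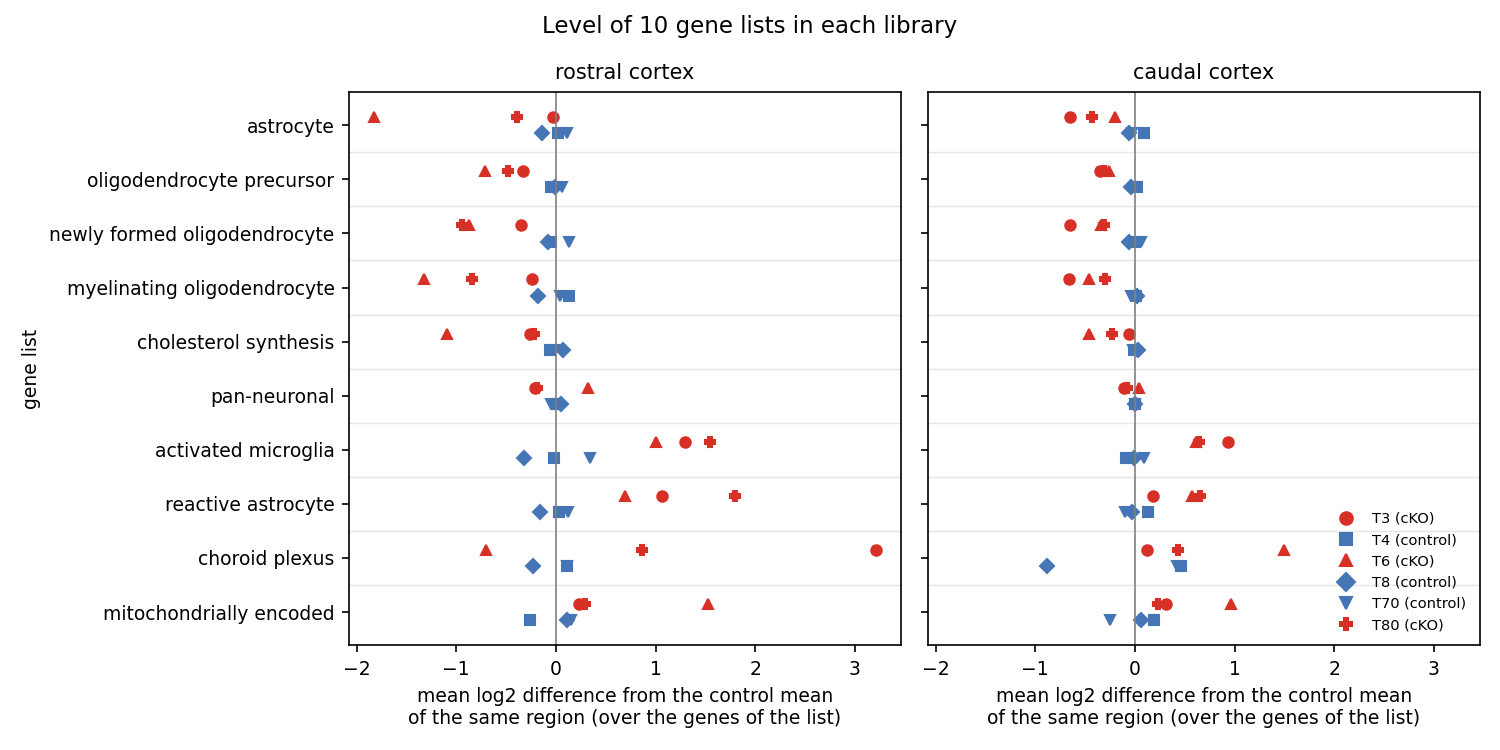
Level of 10 gene lists in each library, as the mean log2 difference from the control mean of the same region over the genes of the list, with blue for control and red for cKO and the animal given by the symbol. In rostral cortex T6 lies at -1.82 for the astrocyte list, and T3 at 3.21 for the choroid plexus list.

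The comparison of cKO with control caudal cortex asks the same question for the caudal piece. Of the members of the fixed lists, 1 of 25 of the astrocyte list, 1 precursor and 1 newly formed oligodendrocyte gene and 0 myelinating genes fell, and Spp1 rose. Spp1 went from 10.3 ± 2.68 CPM (SD, n = 3) in control to 38.0 ± 4.69 CPM in cKO, a log2 fold change of 1.89 (SE 0.19, adjusted p = 0.0283, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Has2, a hyaluronan synthase, rose by 0.99 (SE 0.12, edgeR adjusted p = 0.0393). Olig1 fell from 94.1 ± 2.35 to 59.1 ± 4.0 CPM (-0.67, SE 0.07, edgeR adjusted p = 0.0283), and Bcas1, a marker of oligodendrocytes that begin to myelinate, also fell (-0.65, SE 0.08, edgeR adjusted p = 0.0379).

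Among the genes that fell in caudal cortex were the glial receptor Gpr37l1 (-1.09, SE 0.11), the lipase Pla2g7 (-0.92, SE 0.10), the brain proteoglycan Bcan (-0.81, SE 0.09), Fgfbp3 (-0.78, SE 0.09) and the peptide hormone Apln (-0.72, SE 0.08), each with an adjusted p of 0.0283 in edgeR. Wdfy1 fell with -0.72 (SE 0.06, edgeR adjusted p = 0.0125) and the astrocyte membrane protein Mlc1 with -0.48 (SE 0.06, edgeR adjusted p = 0.0426). Rn7s1 (-3.10, SE 0.21, edgeR adjusted p = 0.00699) and Rn7s2 (-3.23, SE 0.38, edgeR adjusted p = 0.0348) also fell. They are near-identical copies of 7SL RNA whose reads may have been divided between genes, so their values are uncertain. Msr1 (1.70, SE 0.22), Zeb2 (0.52, SE 0.07) and Hmox1 (0.98, SE 0.14) had the next smallest p on the higher side and did not pass, with edgeR adjusted p of 0.0568, 0.0606 and 0.0637.

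The edgeR test called 17 of 20705 genes in caudal cortex, 3 higher and 14 lower, with 3004 at an unadjusted p under 0.05. DESeq2 called 517 and limma voom with library quality weights 373. The groups did not overlap for 22.6% of the genes, where chance gives 10%. The edgeR count moved with every animal: it was 0 without T4, 0 without T8, 5 without T70, 99 without T3, 162 without T6 and 0 without T80, and all 17 genes passed both without T3 and without T6. With sex as a covariate 2 genes passed.

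In caudal cortex 15 of the 37 lists passed camera, 10 higher and 5 lower in cKO, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.169. The astrocyte list had a median log2 fold change of -0.37, with 23 of 25 members lower (adjusted p = 5.24e-09, camera, and adjusted p = 0.568 with an estimated correlation). Of its members 1 passed over all genes and 11 passed adjusted over the list alone, among them Slc7a10 (-0.90, SE 0.12), the fibroblast growth factor receptor Fgfr3 (-0.83, SE 0.11) and Aldh1l1 (-0.73, SE 0.10). Its level was -0.655 in T3, -0.195 in T6 and -0.426 in T80. The caudal library of T3 also lay low for the meningeal fibroblast (-2.16), erythroid (-1.26), pericyte and smooth muscle (-0.537) and endothelial (-0.284) lists. For the meningeal list T6 and T80 were at 0.364 and 0.535. The precursor list of the oligodendrocyte lineage had a median of -0.29, with 13 of 15 lower (adjusted p = 0.000236, camera, and adjusted p = 0.339 with an estimated correlation), 1 of them past the test over all genes and 4 adjusted over the list alone. The list of newly formed oligodendrocytes had a median of -0.38, with 10 of 12 lower (adjusted p = 0.00031, camera, and adjusted p = 0.169 with an estimated correlation), 1 over all genes and 4 adjusted over the list alone. Enpp6 was at -1.02 (SE 0.17). The myelinating list had a median of -0.36, with 12 of 14 lower (adjusted p = 9.2e-05, camera, and adjusted p = 0.169 with an estimated correlation), 0 over all genes and 6 adjusted over the list alone. The myelin genes Cnp and Mbp were at -0.78 (SE 0.12) and -0.44 (SE 0.07). All 18 members of the cholesterol synthesis list were lower, with a median of -0.20 (adjusted p = 4.23e-05, camera, and adjusted p = 0.695 with an estimated correlation). Their level was -0.462 in T6, -0.0578 in T3 and -0.229 in T80.

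The intermediate progenitor and cell cycle lists lay higher in cKO caudal cortex, while the radial glia and neural progenitor list did not pass (median 0.21, adjusted p = 0.757, camera), with levels of -0.229 in T3, 0.248 in T6 and 0.0662 in T80. The intermediate progenitor list had a median of 0.53, with 7 of 8 members higher (adjusted p = 0.00149, camera, and adjusted p = 0.695 with an estimated correlation), 0 over all genes and 4 adjusted over the list alone. Its level was 0.293 in T3, 1.01 in T6 and 0.666 in T80, where the hippocampal list was at -0.182, 0.367 and 0.0509 and the choroid plexus list at 0.119, 1.5 and 0.432. Eomes, a transcription factor of cortical intermediate progenitors, was at 13.1 against 3.76 CPM (1.81, SE 0.37, edgeR adjusted p = 0.159) and Neurog2 at 1.70 (SE 0.34, edgeR adjusted p = 0.134). The G2/M list had a median of 0.32, with 20 of 20 members higher (adjusted p = 5.5e-05, camera, and adjusted p = 0.695 with an estimated correlation). The level of this list was 0.558 in T6 against 0.0256 in T3 and 0.218 in T80. The G1/S list, at 0.20 with 18 of 20 higher, passed camera (adjusted p = 0.0094, and adjusted p = 0.695 with an estimated correlation) but not without T4 (adjusted p = 0.0998) or T80 (adjusted p = 0.262). The ventral-derived neuroblast list, at 0.20 with 10 of 13 higher (adjusted p = 0.0102, camera, and adjusted p = 0.695 with an estimated correlation), had 3 members past the test adjusted over the list alone. Dlx1 was at 0.47 (SE 0.08), and the list did not pass without T8 (adjusted p = 0.118). The rostral-high patterning list was at 0.16 with 9 of 11 higher (adjusted p = 0.0181, camera, and adjusted p = 0.339 with an estimated correlation), and at an adjusted p of 0.0530 without T6.

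Microglial and reactive lists also lay higher in caudal cortex. The activated microglia list had a median of 0.32, with 11 of 13 higher (adjusted p = 0.00031, camera, and adjusted p = 0.169 with an estimated correlation), 1 over all genes (Spp1) and 3 adjusted over the list alone. The microglia list had a median of 0.29, with 13 of 17 higher (adjusted p = 0.00679, camera, and adjusted p = 0.695 with an estimated correlation), and adjusted over the list alone 7 were higher and 1 lower. C1qb, a subunit of complement C1q, was at 17.2 against 10.3 CPM (0.75, SE 0.14). The microglia list did not pass without T8 (adjusted p = 0.0551) or T3 (adjusted p = 0.0594). The reactive astrocyte list, at 0.42 with 11 of 14 higher (adjusted p = 0.0279, camera, and adjusted p = 0.695 with an estimated correlation) and 2 adjusted over the list alone, did not pass without T80 (adjusted p = 0.251) or with the stricter filter on counts (adjusted p = 0.275). The choroid plexus list, at 0.62 with 12 of 13 higher (adjusted p = 0.0281, camera, and adjusted p = 0.872 with an estimated correlation), did not pass without T8 (adjusted p = 0.289) or T6 (adjusted p = 0.703). The mitochondrially encoded list was at 0.54 with 13 of 13 higher (adjusted p = 5.17e-05, camera, and adjusted p = 0.695 with an estimated correlation), and its level was 0.959 in T6, 0.309 in T3 and 0.227 in T80. Median, mean and test direction differed in sign for the pan-neuronal, olfactory bulb, endothelial, meningeal fibroblast, ERBB, interferon and hypoxia lists, none of which passed.

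The sum of the rostral and caudal counts of each animal asks for the effect of genotype over the whole piece. The animal is the replicate, and each region is weighted by the total counts of its library. Rostral and caudal totals were 54680589 and 82056738 in control T4, 67399833 and 65039718 in T8, and 63059556 and 61514024 in T70. In cKO they were 72127917 and 43810241 in T3, 87170063 and 67193765 in T6, and 65031831 and 71048890 in T80. Genes that differ between the regions may thus be among those called on the sum, which was not tested. Besides Egfr, 2 members of the oligodendrocyte precursor list, 1 of the newly formed list and 1 of the astrocyte list fell. Olig1 went from 103 to 55.6 CPM (-0.90, SE 0.07, adjusted p = 0.0115, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 per genotype), Olig2 fell with -0.59 (SE 0.07, edgeR adjusted p = 0.0381), Enpp6 with -1.38 (SE 0.16, edgeR adjusted p = 0.0365) and Slc7a10 with -1.31 (SE 0.14, edgeR adjusted p = 0.0280). Ednrb, the endothelin receptor of glia and their progenitors, fell from 182 to 89.7 CPM (-1.02, SE 0.08, edgeR adjusted p = 0.0115). Myoc (-2.32, SE 0.27, edgeR adjusted p = 0.0354) and Abhd3 (-1.32, SE 0.15, edgeR adjusted p = 0.0344) fell as well. The scavenger receptor Msr1 (2.50, SE 0.31, edgeR adjusted p = 0.0382), the complement receptor C5ar1 (2.09, SE 0.23, edgeR adjusted p = 0.0344), Galnt6 (1.88, SE 0.22, edgeR adjusted p = 0.0344) and Eomes (1.75, SE 0.23, edgeR adjusted p = 0.0491) rose. A 7SK RNA gene also rose (1.65, SE 0.14, edgeR adjusted p = 0.0165), with the uncertainty of such copies. Aqp4, the water channel of astrocyte endfeet, was at 132 against 227 CPM (-0.78, SE 0.11) and did not pass (edgeR adjusted p = 0.0514), nor did Spp1 (2.22, SE 0.36, edgeR adjusted p = 0.0782).

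On the summed counts the edgeR test called 41 of 22924 genes, 19 higher and 22 lower, with 3528 at an unadjusted p under 0.05. DESeq2 called 803 and limma voom with library quality weights 736, and the groups did not overlap for 25.9% of the genes, where chance gives 10%. The edgeR count was 1 without T4, 1 without T8, 2 without T70, 685 without T6 and 18 without T80, and 1 with sex as a covariate. Of the 41 genes, only Egfr itself passed without T4, without T8, without T70 and with sex as a covariate. Its edgeR adjusted p was 0.0302, 0.0153, 0.0212 and 0.0042 in these fits. None of the other genes named above as fallen or risen passed in any of these fits. The astrocyte list had a median of -0.37, with 1 member past the test over all genes and 12 adjusted over the list alone (adjusted p = 5.68e-10, camera, and adjusted p = 0.49 with an estimated correlation). The activated microglia list had a median of 0.96 with 14 of 15 members higher and 11 past the test adjusted over the list alone (adjusted p = 1.48e-06, camera, and adjusted p = 0.23 with an estimated correlation). The lists of oligodendrocyte precursors (-0.41), newly formed (-0.35) and myelinating oligodendrocytes (-0.49) passed camera as well, with adjusted p of 3.06e-06, 5.39e-06 and 1.74e-06, and adjusted p of 0.23, 0.29 and 0.44 with an estimated correlation. Without T6 the median of the cholesterol synthesis list moved from -0.37 to -0.19, and that of the mitochondrially encoded list from 0.81 to 0.27.

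**Figure D4:**
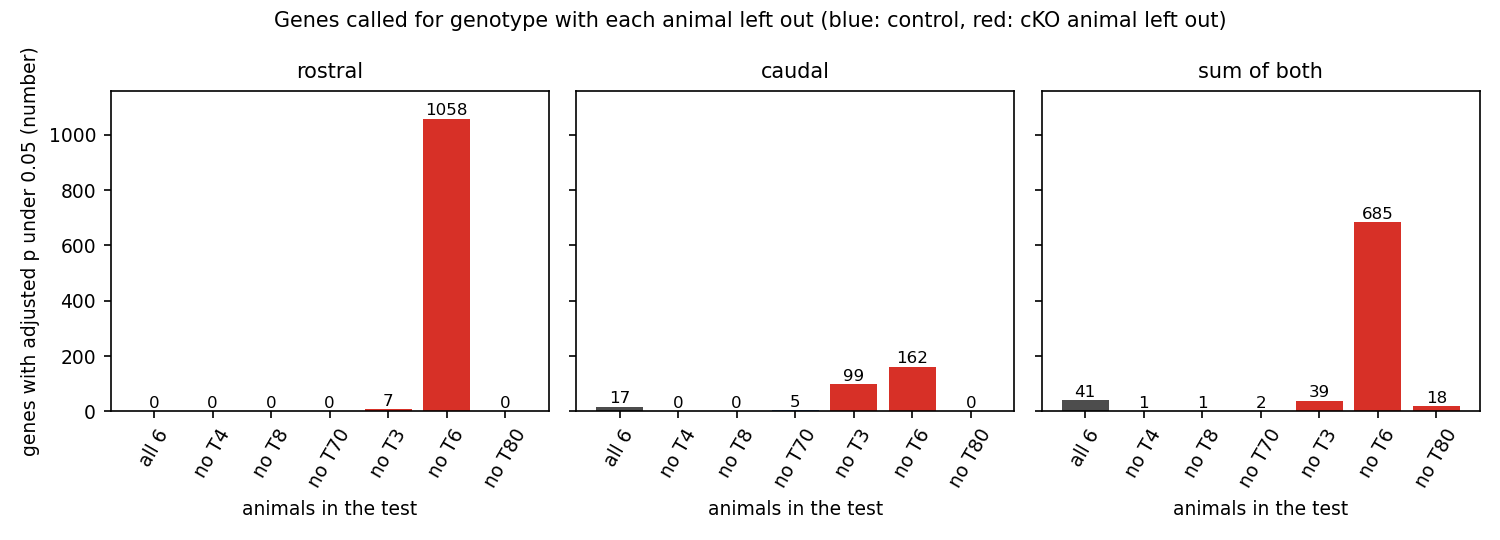
Number of genes with an adjusted p under 0.05 (edgeR quasi-likelihood test) for cKO against control, with all 6 animals and with each animal left out, in rostral cortex, caudal cortex and the sum of both. The bars reach 1058, 162 and 685 genes without T6.

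Whether the genotype effects of both regions resemble each other was asked by correlating the log2 fold changes of all genes tested in both. Across 20185 genes Pearson's r was 0.505 and Spearman's rho 0.482, with 70.8% of genes on the same side of 0. For genes with a mean CPM of 10 or more (10144 genes) r was 0.682 and rho 0.648. Both regions come from the same animals, so differences between animals give a correlation above 0 even without an effect. Without T6, r was 0.217 and rho 0.167.

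The comparison of caudal with rostral cortex in control animals asks how the regions differ when Egfr is present. Of the hippocampal list 6 of 17 members and of the caudal-high patterning list 4 of 14 were higher in the caudal piece. Among genes of cortical layers more were lower than higher there, 5 against 2 of the upper-layer and 7 against 2 of the deep-layer list. Fibcd1, a marker of hippocampal CA1 neurons, was at 26.2 CPM in caudal and 4.20 CPM in rostral cortex (2.64, SE 0.09, adjusted p = 2.08e-07, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 per region). Nr2f2, a transcription factor of caudal cortex, was at 92.4 against 21.1 CPM (2.13, SE 0.14, edgeR adjusted p = 0.000141). Syt6, a marker of deep-layer neurons, was at 20.2 against 72.5 CPM (-1.84, SE 0.09, edgeR adjusted p = 8.23e-06). Egfr did not differ by this test (-0.06, SE 0.09, edgeR adjusted p = 0.693).

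The genes with the largest differences in control were Dsc3 (4.99, SE 0.22), Gpr101 (4.87, SE 0.55), Chrm5 (3.78, SE 0.25), the synaptic organiser Cbln4 (3.40, SE 0.15) and Lhx9 (3.15, SE 0.30) on the caudal side, followed by Htr5b (2.90), Car12, Pde11a and Olfm4 (each 2.77) and Cr2. On the rostral side were Rxfp2 (-2.77, SE 0.19), Ostn (-2.50, SE 0.30), the serotonin transporter Slc6a4 (-2.11, SE 0.31) and Lmod3 (-1.87, SE 0.25), followed by Syt6, Rgs9bp, Susd5, Cyp26b1, an enzyme that breaks down retinoic acid, Mc4r and the zinc transporter Slc30a3 at -1.84 to -1.49. Their edgeR adjusted p ran from 5.86e-06 for Car12 to 0.00421 for Slc6a4. Of these 20 genes, Cyp26b1 did not pass without T8 (-1.63, edgeR adjusted p = 0.0553), and Gpr101 (4.93, edgeR adjusted p = 0.0606) and Slc6a4 (-2.07, edgeR adjusted p = 0.0812) did not pass without T70.

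The edgeR test called 2492 of 20461 genes between the control regions, 1289 higher and 1203 lower in caudal cortex. This test did not use the pairing of libraries within an animal, and with the animal as a block 3144 genes passed. The groups did not overlap for 31.4% of the genes, where chance gives 10% for independent libraries, which these pairs from the same animals are not. The count was 1079 without T8 and 1487 without T70.

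Between the control regions 22 of the 37 lists passed camera, 13 higher and 9 lower in caudal cortex, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.415. The hippocampal list had a median of 0.39, with 14 of 17 higher (adjusted p = 0.00057, camera, and adjusted p = 0.415 with an estimated correlation). Over all genes and adjusted over the list alone 6 passed, among them Prox1, a transcription factor of dentate granule cells (1.41, SE 0.17, and an edgeR adjusted p of 0.0524 without T70), and C1ql2 (1.92, SE 0.27). The choroid plexus list had a median of 1.75, with 13 of 13 higher (adjusted p = 9.27e-07, camera, and adjusted p = 0.415 with an estimated correlation), 7 over all genes and 12 adjusted over the list alone. The ependymal list had a median of 1.03, with 12 of 12 higher (adjusted p = 9.27e-07, camera, and adjusted p = 0.415 with an estimated correlation), 5 over all genes and 11 adjusted over the list alone. The caudal-high patterning list had a median of 0.24, with 10 of 14 higher (adjusted p = 0.00859, camera, and adjusted p = 0.415 with an estimated correlation) and 4 past the test over all genes, with Crym at 2.09 (SE 0.17). It did not pass without T70 (adjusted p = 0.127). The thalamus list was at 0.29 (adjusted p = 0.0125, camera, and adjusted p = 0.415 with an estimated correlation), with 5 members higher and 2 lower over all genes. Slc17a6, a vesicular glutamate transporter, was at 0.73 (SE 0.08). The meningeal fibroblast list was at 0.83 with 15 of 15 higher (adjusted p = 2.64e-05, camera, and adjusted p = 0.474 with an estimated correlation) and 2 past the test.

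The upper-layer list had a median of -0.37 (adjusted p = 0.0189, camera, and adjusted p = 0.437 with an estimated correlation), with 2 members higher and 5 lower in caudal cortex over all genes, and 3 and 7 adjusted over the list alone. It did not pass without T8 (adjusted p = 0.0743). The deep-layer list had a median of -0.24 but a mean of 0.01, with Crym at 2.09 (adjusted p = 0.0171, camera, direction down, and adjusted p = 0.415 with an estimated correlation). Of its members 2 were higher and 7 lower over all genes, among them Tbr1 (-0.45, SE 0.05) and Sox5 (-0.50, SE 0.05), and it did not pass without T70 (adjusted p = 0.0820). The ventral-derived neuroblast list was at -0.35 (adjusted p = 0.0189, camera, and adjusted p = 0.486 with an estimated correlation), with 1 member higher and 3 lower, and at an adjusted p of 0.0905 without T70. The cortical interneuron list was at 0.27 (adjusted p = 0.00594, camera, and adjusted p = 0.437 with an estimated correlation), with 5 higher, such as Cort (1.57, SE 0.15), and 1 lower.

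Glial and progenitor lists divided between the regions. The oligodendrocyte precursor list was at -0.23 (adjusted p = 0.00199, camera, and adjusted p = 0.415 with an estimated correlation), with 1 member higher and 4 lower over all genes, among them Olig1 (-0.36, SE 0.05). The lists of newly formed (-0.26) and myelinating oligodendrocytes (-0.34) also lay on the rostral side, with camera adjusted p of 0.00405 and 0.00601, and adjusted p of 0.415 and 0.474 with an estimated correlation. Tnr, an extracellular matrix protein of the lineage, fell from 329 to 184 CPM towards caudal cortex (-0.84, SE 0.07, edgeR adjusted p = 3.57e-05). The astrocyte list was at 0.14 with 19 of 25 higher (adjusted p = 0.0189, camera, and adjusted p = 0.623 with an estimated correlation). Over all genes 5 members were higher, among them Gfap (0.94, SE 0.11), and 2 lower. The list did not pass without T4 (adjusted p = 0.174). The microglia list, at 0.17 (adjusted p = 0.0336, camera, and adjusted p = 0.658 with an estimated correlation), did not pass without T4 either (adjusted p = 0.135). The activated microglia list was at 0.23 (adjusted p = 0.0122, camera, and adjusted p = 0.474 with an estimated correlation). The intermediate progenitor list had a median of 0.64, with 5 of 8 higher and 3 past the test, Neurog2 (2.14, SE 0.39) and Neurod1 among them (adjusted p = 0.0455, camera, and adjusted p = 0.486 with an estimated correlation). It did not pass without T8 (adjusted p = 0.0743), without T70 (adjusted p = 0.0820), with the stricter filter (adjusted p = 0.131) or with the animal as a block (adjusted p = 0.0717).

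The remaining lists called between the control regions were the mitochondrially encoded list at -0.70 with 13 of 13 lower and 11 past the test (adjusted p = 8.91e-07, camera, and adjusted p = 0.437 with an estimated correlation). They include the G2/M list at -0.32 with 20 of 20 lower and 0 past the test (adjusted p = 6.64e-05, camera, and adjusted p = 0.486 with an estimated correlation). The cholesterol synthesis list was at -0.09 with 18 of 18 lower (adjusted p = 0.00279, camera, and adjusted p = 0.474 with an estimated correlation). Hmgcs1 was at -0.32 (SE 0.07) and did not pass without T8 (edgeR adjusted p of 0.10) or T70 (0.147). The immediate early list was at 0.17 with 11 of 15 higher (adjusted p = 0.00562, camera, and adjusted p = 0.415 with an estimated correlation). The 6 members past the test include Bdnf (1.05, SE 0.10) and Fos (0.75, SE 0.12). The interferon list was at 0.35 with 12 of 14 higher (adjusted p = 0.0171, camera, and adjusted p = 0.415 with an estimated correlation), and did not pass without T8 (adjusted p = 0.0668) or with the stricter filter (adjusted p = 0.0815).

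The same comparison in cKO asks how the regions differ there. The edgeR quasi-likelihood test called 0 of 20944 genes, with 348 at an unadjusted p under 0.05, and DESeq2 called 4 and limma voom with library quality weights 0. In simulated counts this test recovered 34.3% of genes changed 2-fold, against 92.5% between control regions. The 0 therefore does not show that the regions no longer differ. From the rostral to the caudal library the region score went from 0.855 to 0.557 in T3, -0.0783 to 1.15 in T6 and 0.638 to 0.811 in T80. Sema3c, a secreted guidance cue (0.59, SE 0.13), Neurod1 (0.84, SE 0.21), Lefty2 (0.60, SE 0.14), Strip2 (0.81, SE 0.20) and Syt2 (1.15, SE 0.29) had the smallest p on the caudal side. The tachykinin receptor Tacr1 (-1.07, SE 0.22), Bhlhe40 (-0.56, SE 0.13), Dnah8 (-0.66, SE 0.16), mt-Nd3 (-0.71, SE 0.14) and mt-Rnr2 (-0.61, SE 0.15) had the smallest p on the rostral side, and none passed (adjusted p of 1 in edgeR, n = 3 per region). The groups did not overlap for 5.76% of the genes. Chance gives 10% only for independent libraries, and these are pairs from the same animals, so the shares are not directly comparable. Of the lists 13 passed camera, and 0 with an estimated correlation, among them the ependymal list at 0.71 with 12 of 12 higher (adjusted p = 3.1e-10, and adjusted p = 0.588 with an estimated correlation) and the astrocyte list at 0.37 with 24 of 25 higher (adjusted p = 3.05e-07, and adjusted p = 0.696 with an estimated correlation). Relative to the control rostral mean, the astrocyte level went from -1.82 in the rostral to -0.0116 in the caudal library of T6 and from -0.386 to -0.242 in T80, and the other way in T3, from -0.0330 to -0.471.

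The interaction of genotype and region asks whether the genotype effect differed between rostral and caudal cortex. The edgeR quasi-likelihood test called 0 of 21599 genes, with 767 at an unadjusted p under 0.05, 271 with a higher effect in caudal cortex and 496 with a lower effect. DESeq2 called 14 genes and limma voom with library quality weights 149. Cr2 had the smallest adjusted p (-2.72, SE 0.38, edgeR adjusted p = 0.263), followed by the serotonin receptor Htr1a (-1.62, SE 0.27) and Smtnl2 (-0.89, SE 0.15), both with an edgeR adjusted p of 0.486, Clrn1 (-2.04, SE 0.42, edgeR adjusted p = 0.958) and Dsc3 (-4.75, SE 1.03, edgeR adjusted p = 1). On the other side Kcnj10 (0.92, SE 0.20), Abcd2 (0.59, SE 0.13), Ephb1 (0.51, SE 0.11), Ptger4 (0.91, SE 0.21) and Emid1 (0.68, SE 0.16) had the smallest p and did not pass. For Egfr the interaction was 0.10 (SE 0.41, edgeR adjusted p = 1). The count was 475 without T6 and 1 without T3.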

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

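The tests chosen only after the result was seen are the gap between pan-neuronal and astrocyte lists and the astrocyte level in cKO rostral T6, the choroid plexus and hippocampal levels under an exchange of the labels of T3, and the tests of sex, of animal T6 alone and of the share of brain parenchyma for the glial lists. They replaced or joined earlier tests that decided nothing: the median deviation of cKO rostral T6 was the same with and without mitochondrial genes (0.403), the region score of cKO caudal T3 (0.557) lay among those of the cKO rostral libraries, and the median of the pan-neuronal list alone was 0.0322.

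Camera on the interaction called 13 gene lists for a genotype effect that differed between rostral and caudal cortex, with 3 animals per genotype. With an estimated correlation the lowest adjusted p in camera was 0.441. The other splits of the animals called 17, 14, 5, 19, 16, 6, 2, 18 and 16 lists, so 13 was not an unusual count. The effect was higher in caudal than in rostral cortex for the G2/M (adjusted p = 1.56e-08), cholesterol synthesis (0.000365), G1/S (0.00108), myelinating oligodendrocyte (0.00277), deep-layer neuron (0.00277), striatum (0.00277), newly formed oligodendrocyte (0.0041), astrocyte (0.00412) and oligodendrocyte precursor (0.0108) lists. It was lower in caudal cortex for the reactive astrocyte (adjusted p = 0.000105), cortical interneuron (0.00108), activated microglia (0.00412) and thalamus (0.0329) lists. The direction rested on T6 for the astrocyte list, at -0.195 in its caudal and -1.82 in its rostral library, where T3 (-0.655 and -0.0330) and T80 (-0.426 and -0.386) lay lower in caudal cortex. In T3 the myelinating (-0.667 and -0.239), newly formed (-0.655 and -0.350) and precursor (-0.349 and -0.328) lists also lay lower in caudal cortex, and the cholesterol synthesis list was at -0.229 and -0.224 in T80 and at -0.462 and -1.10 in T6. T6 ran against the stated direction for the thalamus list (0.124 in caudal and -0.104 in rostral cortex, with -0.211 and 0.681 in T3) and for the deep-layer list (-0.0191 and -0.0106).

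The cKO rostral library of T6 stood apart, with a mitochondrial share of 8.18% against at most 3.98% in any other library, an astrocyte level of -1.82 and a meningeal level of -3.56. Mitochondrial reads that take the place of other reads would lower every list alike, but its pan-neuronal and astrocyte lists lay 2.15 log2 units apart, against at most 0.339 in the other libraries when all are set against the control rostral mean (against its own region, cKO caudal T3 was at -0.106 and -0.655). A bias by gene length is argued against by a Spearman's rho across genes of 0.0156 between exonic length and deviation, where the largest in another library was -0.191. Less pia and vessel in the piece was judged by the astrocyte list, assumed to be spared, which lay at -1.44 relative to the lower of the other cKO rostral libraries. This cannot decide, since astrocyte and meningeal levels were lowest in the same libraries. They were at -1.82 and -3.56 in cKO rostral T6 and at -0.655 and -2.16 in cKO caudal T3. Less pia and vessel therefore stays open. A piece of another layer composition, other handling of the tissue, or a stronger effect of genotype in this animal may lie behind it, and none of these was tested.

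The cKO rostral library of T3 held choroid plexus (3.21) and hippocampal transcripts (0.661) above the control rostral mean. Had its labels been exchanged with the caudal library of T3, that library would still stand above every other rostral library, with 2.27 for the choroid plexus list (highest other 0.860, SD of control rostral libraries 0.198) and 0.418 for the hippocampal list (highest other 0.115, SD 0.0707), but the region score alone, 0.855 in its rostral and 0.557 in its caudal library, leaves the order of the labels open. Caudal tissue in the rostral piece is a candidate explanation: genes lower in control caudal cortex scored 0.589 and genes higher there 0.932 on the way to the control caudal mean. The cKO rostral library of T80 scored 0.526 on the first of these gene sets, so a loss of regional difference with genotype stays open as a hypothesis, as does a dissection plane that differed between animals. The interaction fit bears on a loss of regional difference but does not decide it: edgeR called 0 of 21599 genes with all animals and 475 without T6. In T6 the regions scored apart over all region genes, at -0.0783 in rostral and 1.15 in caudal cortex. Its rostral library stood apart in meningeal (-3.56), choroid plexus (-0.697) and mitochondrial (1.53) levels, lists that also differed between the control regions. The score of this 1 library therefore cannot decide whether a regional difference was kept in that animal. The dissection plane was not tested.

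By camera, lists of astrocytes and oligodendrocytes were lower in cKO in both regions, with an astrocyte median of -0.374 on the summed counts, but none passed with an estimated correlation (adjusted p = 0.49 for astrocytes and 0.23, 0.29 and 0.44 for the oligodendrocyte lists on the summed counts), and the rostral astrocyte level was -0.0330 in T3, inside the control range of -0.138 to 0.113, and -1.82 in T6. Unequal sex is argued against as the whole cause, since the median was -0.362 with sex as a covariate, and so is animal T6 alone, since it was -0.309 without T6. A lower share of parenchyma would lower neuronal markers alike, but the astrocyte median lay at -0.406 relative to the pan-neuronal median, and at -0.15 without T6 to -0.663 without T80, although without T6 the pan-neuronal list itself lay at -0.159. A lower number or later maturation of glial cells after the loss of Egfr may account for these values as a hypothesis, found and tested on the same animals. A litter or dissection that differs between genotypes was not tested, nor was the unequal mix of regions in the summed counts. An effect of the recombinase itself was not tested either, and the labels do not say whether the controls carry it.

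With 3 animals against 3 there are 10 splits, which are too few for a share under 0.05. For genotype in rostral cortex 10 of the 10 splits gave as many genes as the real one (0, highest other 4), in caudal cortex 1 (17, highest other 9) and on the summed counts 1 (41, highest other 8). For region in control 1 split gave as many (2492, highest other 0, with 3 of the other splits parting every animal's pair as the real one does), for region in cKO 10 (0, highest other 0) and for the interaction 10 (0, highest other 1). For the list tests 7 splits gave as many in rostral cortex (12, highest other 21), 3 in caudal cortex (15, highest other 17) and 1 between control regions (22, highest other 15). For the interaction the other splits called 2 to 19 lists, against 13 in the real one. Pearson's correlation of the genotype effects was as high in 2 splits (0.505, highest other 0.543), and Spearman's rho of 0.482 was exceeded by 0.483 in the split with T4, T70 and T80 together and by 0.522 in that with T4, T8 and T80. The split of T4, T8 and T3 against T70, T6 and T80 is the split by sex, and it gave the 4, 9 and 8 genes and the correlation of 0.543 (rho 0.294), while with sex as a covariate the real comparison called 0, 2 and 1 genes.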

How the results depend on the processing

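The alternatives chosen only after the data were seen are library quality weights, the removal of the cKO rostral libraries of T3 and T6, the removal of mitochondrial genes and the exchanged labels of T3. Called genes named in the text stayed called in 927 of 1119 refits and lost the call with the same sign in 192. Named genes not called stayed so in 1222 of 1557 and became called in 324, and called lists stayed called in 285 of 382. This tally pools the genes of the region comparison with those of genotype. For genotype, 0 of the 17 calls in caudal cortex held without T4, T8 or T80. On the summed counts 1 of 41 held without T4, T8 or T70, and it was Egfr, the deleted gene. With each animal left out, the number of called genes ran from 0 to 1058 in rostral cortex, 0 to 162 in caudal cortex, 1 to 685 on the summed counts, 1079 to 1690 between control regions and 0 to 475 for the interaction, the lists called in rostral cortex from 12 to 20, and the correlation of effects from 0.217 to 0.590 (rho 0.167 to 0.550). DESeq2 called 394 genes in rostral cortex, 517 in caudal cortex, 803 on the summed counts, 4 between cKO regions and 14 for the interaction. Without a filter on low counts 45, 326 and 320 genes passed for genotype and 2 for the interaction. A fit over all 12 libraries called 101 genes in rostral and 1 in caudal cortex. Sex as a covariate left 2 genes in caudal cortex and 1 on the summed counts, which was Egfr. The range of the T number as a covariate gave 1 in rostral cortex, 5 in caudal cortex and 20 on the summed counts. Quality weights called 974, 373 and 736 genes for genotype and 149 for the interaction, with a weight of 0.104 for cKO rostral T6. With T6 left out or weighted down, the rostral cKO values rest mainly on T3 and T80, which scored 0.855 and 0.638 towards caudal cortex. Without the cKO rostral libraries of both T3 and T6, where the lone cKO library is assumed to vary like the other groups, 1047 genes passed in rostral cortex and 57 for the interaction, against 35 without that of T6 and 1 without that of T3. The average over both regions with duplicateCorrelation called 80 genes, and 263 without those libraries. With the labels of T3 exchanged, 455 genes passed in caudal cortex, 12 of the 17 among them. With an estimated correlation 0 lists passed in rostral cortex, in caudal cortex and between control regions, and between control regions also with the animal as a block. For genes with a mean CPM of 10 or more the correlation was 0.682 (rho 0.648). Egfr, not called between regions, changed sign under several alternatives. With each animal left out its log2 fold change ran from -0.164 to 0.0528 between control regions, from -0.574 (without T6) to 0.357 between cKO regions and from -0.497 (without T6) to 0.417 for the interaction, where it was -0.0174 without T70. Between cKO regions it was -0.0266 with the animal as a block, -0.257 with quality weights, -0.184 without cKO rostral T6 and -0.306 without both doubted libraries, and for the interaction -0.204, -0.104 and -0.237 under the last 3 of these. For all of these the cause was not tested. The animal as a block gave 3144 genes between control regions, 0 between cKO regions and 0 for the interaction (943 at an unadjusted p under 0.05), ended the call of the intermediate progenitor list between control regions (adjusted p = 0.0717), let Cenpe of the G2/M list pass there, and changed no other call of a named gene or list and no count by over 1.5 times. For genes with 100 or more counts the spread between animals exceeded counting error, and for genes with fewer counts depth adds to it. In simulated data without T6 (20846 genes) edgeR recovered 58.2% of genes changed 1.5-fold in rostral cortex, against 4.48% with T6 (20518 genes).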

Other observations

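No test in this part was chosen only after its result was seen, but the pituitary test was judged unable to decide afterwards, and Gh, Plek and the mitochondrial genes were picked after their values were seen. Other members of the receptor family and its ligands went both ways on the summed counts. The list of ERBB receptors and ligands had a median log2 fold change of -0.02 over 14 genes (camera adjusted p = 0.75). Of its members 1 was higher and 1 lower adjusted over the list alone, and 0 passed over all genes. The fry test gave it an adjusted p of 0.723 for direction and 0.000182 for mixed directions. A low mixed value was not particular to it: fry gave 0.000182 for the oligodendrocyte precursor and 0.000301 for the radial glia list. Hbegf, a ligand of the receptor, was at 14.7 against 18.7 CPM (-0.35, SE 0.07, edgeR adjusted p = 0.119, n = 3 per genotype), Tgfa at 34.1 against 54.8 CPM (-0.69, SE 0.21, edgeR adjusted p = 0.236), and Erbb4 at 102 against 85.3 CPM (0.26, SE 0.07, edgeR adjusted p = 0.201). None of them passed over all genes.

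Feedback genes of receptor tyrosine kinase and MAPK signalling went both ways on the summed counts. Their list had a median of 0.13 over 18 genes, with 11 higher and 7 lower. Its camera adjusted p was 0.229, and its fry adjusted p 0.128 for direction and 0.0192 for mixed directions. Adjusted over the list alone 1 member was higher and 1 lower. Dusp4, a phosphatase of MAP kinases, was at 27.6 against 16.5 CPM (0.74, SE 0.11, edgeR adjusted p = 0.0578), and the transcription factor Etv4 at 11.5 against 16.8 CPM (-0.54, SE 0.13, edgeR adjusted p = 0.18).

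Counts of Gh, the growth hormone gene, were 0 in all 6 control libraries and 11 to 22 in all 6 cKO libraries. Pituitary tissue in the pieces stays open: the summed counts of Prl, Pomc, Tshb, Lhb, Cga and Pou1f1 in cKO were, as a share of the library, 1.03 times those in control, but they were 22 to 81 in the control libraries and mostly Pomc, a baseline that would hide the few counts such tissue could add. Growth hormone sequence carried by the recombinase transgene may be counted as Gh, which was not tested, as the sources used here do not give the transgene.

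Genes linked to the floxed Egfr allele could differ between genotypes because of another strain around it. Of 98 genes within 10 Mb of Egfr, 15 had an unadjusted p under 0.05 on the summed counts, 15.3% against 15.4% elsewhere, a ratio of 0.995, and 508 of 1000 random windows had as high a share. The smallest p among them was that of Plek (0.86, edgeR adjusted p = 0.0840).

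The residual Egfr level differed between the pieces of single cKO animals, at 10.3 and 5.73 CPM in rostral and caudal cortex of T3, 6.39 and 14.7 CPM in T6, and 12.6 and 9.53 CPM in T80. Some mitochondrial genes had few counts where nuclear copies had many: mt-Co2 had a mean of 1.63 CPM and mt-Co3 2.54 CPM, where mt-Co1 had 7713 CPM and the copies Gm10925, Gm28437 and Gm28661 on chromosome 1 had 10617, 5521 and 4138 CPM. Reads of the former may have been counted at such copies, which was not tested. The interferon list lay at 2.10 in cKO rostral T80 and between -0.662 and 0.402 in the other cKO libraries.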
